A study of Mus musculus with 2 samples.

How the data were processed

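Single-cell RNA-seq was carried out on mouse E14 embryonic stem cells, a male line that divides without limit in culture and can form all tissues of the embryo. Per the labels, the cells were grown without feeder cells in medium with 2 kinase inhibitors and leukaemia inhibitory factor (2i/LIF), and were treated for 24 h with DMSO, the solvent, or with Idoxuridine, an iodinated thymidine analogue that is built into newly made DNA. The treatment label gives the dose as 10 µM, and a protocol field gives 10 mM. The dose label of 10 µM is used here, and the conflict is left open. There was 1 library per treatment, and each sample was put in its group by its treatment label.

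Per the labels, the libraries were made on a 10x Genomics Chromium instrument with 3′ V2 chemistry, in which each transcript end carries a unique molecular identifier (UMI) that removes PCR copies, and were sequenced on an Illumina HiSeq instrument. Cell Ranger 2, Seurat and the mouse build mm10 are named per the submitters' processing notes. The notes used here do not say which step each tool carried out. The deposited values are counts: whole-number UMI counts per gene and cell, not normalized, for 27998 genes in both libraries. How the authors chose the barcodes deposited as cells, and the annotation release behind the counts, were not given in the sources used here. All deposited barcodes were therefore taken as cells, with 811 in the DMSO library and 742 in the Idoxuridine library. Gene coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, and 27645 of the 27998 gene identifiers (98.7%) were found there.

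Cells of 1 library are not replicates. With 1 library per group no test between the treatments was possible, and no p-value or standard error is given. For the level of a gene, UMIs were summed over all cells of a library and scaled to counts per 10⁶ UMIs (CPM). Each CPM has an exact Poisson 95% interval and each ratio an exact conditional binomial interval. These intervals, and the exact binomial (Clopper-Pearson) intervals of shares, cover counting error only, not the spread between cultures. Genes with at least 200 UMIs over both libraries were counted by size, as at least 0.5 log2 higher or lower in the Idoxuridine library with Poisson intervals that did not overlap. A ratio against a library with a count of 0 was computed against a floor of 3 counts in that library.

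For the spread between cells, each cell was thinned to 23500 UMIs, the largest multiple of 500 not above the 10th percentile of UMIs per cell over both libraries pooled. The exact expectation of thinning without replacement was used, not a random draw. Shallower cells were left out, which were 47 DMSO cells (5.80%) and 94 Idoxuridine cells (12.7%). The Fano factor is the variance of UMIs per cell over their mean, and is 1 where counting alone sets the spread. The counting-corrected CV² is the squared coefficient of variation less its counting part. Both were computed for genes with a thinned mean of at least 0.25 UMI per cell in both libraries, and the CV² ratio for those where both values were above 0. Cell cycle phases, marker shares and cell-to-cell correlations were computed on 1 seeded random thinning to the same depth. Phases were called by scanpy 1.11.5 from the S phase and G2/M gene lists that Seurat distributes.

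Genes were grouped in 31 lists, and 11 of their 596 genes given by symbol were not found in the gene table. The lists covered general and naive pluripotency, formative or primed cells, 2-cell-embryo-like cells, primitive endoderm, trophectoderm, mesendoderm, neuroectoderm, fibroblasts, p53 targets, base excision repair, strand break repair and checkpoint, mismatch and nucleotide excision repair, nucleotide metabolism, replication, S phase, G2/M, topoisomerases, heat shock, immediate early genes, unfolded protein and integrated stress responses, glycolysis and hypoxia, cholesterol synthesis, the circadian clock, interferon response, germline genes held down by promoter methylation, housekeeping genes, nuclear-retained RNAs, mitochondrially encoded genes, ribosomal protein genes and replication-dependent histones. A list's median ratio is over its members with at least 50 UMIs. Its percentile is that of the median among 10000 random lists of the same size and similar expression, and describes these libraries only. Lists with under 3 members have no median.

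These lists, the measures, the main alternatives and the rule for named genes were fixed before the data were examined. Another 4 lists and 4 tests of explanations, given under the other observations, were chosen after values had been seen. The rule named the 12 genes with the highest and the 12 with the lowest level ratio among those with at least 200 UMIs and separate intervals. It also named the 10 genes with the highest and the 10 with the lowest Fano ratio whose level ratio lay within 0.5 log2, up to 4 members of each list by size of level ratio and up to 4 by size of Fano ratio, and 13 fixed genes: Pou5f1, Sox2, Nanog, Klf4, Esrrb, Cdkn1a, Mdm2, Apex1, Tk1, Per2, Cry1, Actb and Gapdh. Mitochondrially encoded and ribosomal protein genes were summarised, not named, and predicted genes were named only within the top 5. Some single genes that the rule names are not reported. Alternatives covered edgeR 4.0.16 TMM factors, median-of-ratios scaling, 2 other scalings, other count minimums, cell filters on mitochondrial share, depth and Scrublet doublets, other depths or no thinning, cells of 1 phase, and other marker thresholds. Another 7 alternatives were added after the data were seen. No doublets were removed in the main analysis.

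The estimators were tested on simulated counts with the real depths of both libraries and with gene means and variances taken from the DMSO library (10133 genes). Genes nearly silent in DMSO were not covered, and genes were drawn independently of each other. All of the 193 genes given a 2-fold change and tested passed the size limit (100%), against 6 of 9755 unchanged genes. A change of 2 log2 in the cell-to-cell variance was returned as a median of 2.01 and one of 1 log2 as 0.91. Among unchanged genes the thinned Fano factor was higher in 49.96% of genes, and without thinning in 19.1%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.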

Results

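The series asks how a drug used as an enhancer of gene expression noise, that is, of differences between cells at a similar mean level, alters mouse embryonic stem cells. Its title places this in work on cell-to-cell differences in circadian period. The data are 2 single-cell RNA libraries of E14 cells, 1 after 24 h in DMSO and 1 after 24 h in Idoxuridine (10 µM per the treatment label). The DMSO library held 40818344 UMIs in 811 cells, with a median of 44502 UMIs (14814 to 136231) and 6539 genes per cell. The Idoxuridine library held 30454626 UMIs in 742 cells, with a median of 37425 UMIs (9295 to 130052) and 6478 genes per cell. The median mitochondrial share was 2.56% of UMIs in DMSO cells and 2.81% in Idoxuridine cells, and 2 and 1 cells, respectively, were above 10%. There was no replicate library, so every difference below is between these 2 libraries and has no replicate check. Intervals in parentheses are 95% intervals for counting error only.

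The comparison of expression level asks which genes differed in abundance between the treated and the solvent library. Dppa3, a maternal and naive-state factor that protects DNA methylation in the early embryo, stood at 4.75 CPM (4.11 to 5.47) in DMSO and 98.0 CPM (94.5 to 102) in Idoxuridine, a log2 ratio of 4.37 (4.16 to 4.58). Phlda2, an imprinted regulator of placental growth, stood at 2.16 CPM (1.73 to 2.66) and 62.5 CPM (59.7 to 65.4), a log2 ratio of 4.86. Lefty2, a secreted inhibitor of Nodal signalling, was lower in Idoxuridine, at 18.8 CPM (17.3 to 20.5) against 89.3 CPM (86.5 to 92.3), a log2 ratio of -2.25 (-2.37 to -2.12). Tcl1, a co-activator of the kinase Akt that is highly expressed in naive stem cells, stood at 168 CPM (164 to 172) in DMSO and 49.9 CPM (47.4 to 52.5) in Idoxuridine, a log2 ratio of -1.75. Spp1, which encodes the secreted protein osteopontin, had the highest abundance among the 12 genes with the lowest ratios, at 760 CPM (751 to 768) and 302 CPM (296 to 308).

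The 12 genes with the highest ratios were nearly silent in the DMSO library, at 2.16 CPM or less. They were Gm5662 (log2 ratio 7.13, interval 5.57 to 9.42, from 3 and 314 UMIs), Khdc1c (6.66), Bglap3 (6.46), the glycosyltransferase gene Mgat4c (6.14), the germ cell surface protein gene Tex101 (5.89), Ldoc1 (5.59), the galectin gene Lgals7 (5.47), S100a14 (5.02), Phlda2, Tesc (4.85), Krtdap (4.67) and 1 predicted gene with no named function. At the fixed depth, Lgals7 had a UMI in 1.96% of DMSO cells and 46.8% of Idoxuridine cells, and Ldoc1 in 0.963% and 23.1%. The 12 with the lowest ratios were Vax2os (-2.36, interval -2.98 to -1.80), Lefty2, 2310003L06Rik (-2.16), the growth factor gene Fgf17 (-1.81), Tcl1, the stem cell factor receptor gene Kit (-1.65), the complement gene Cfp (-1.45), the pepsinogen gene Pga5 (-1.43), the lysophosphatidic acid receptor gene Lpar4 (-1.42), Ly6g6e (-1.36), Spp1 (-1.33) and the quinone reductase gene Nqo2 (-1.30). Kit had a UMI in 50.5% of DMSO cells and 20.2% of Idoxuridine cells at that depth. On GRCm38, Gm5662 lies at chromosome 12, 88270640 to 88274500, Phlda2 at chromosome 7, 143501545 to 143503150, Dppa3 at chromosome 6, 122626410 to 122630272, Lefty2 at chromosome 1, 180893108 to 180899103, and Tcl1 at chromosome 12, 105216750 to 105222793, all annotated as protein-coding. Gm5662, Khdc1c and Bglap3 have close sequence relatives, 2310003L06Rik overlaps Gm28434 on the same strand, and Vax2os, Nqo2, Ly6g6e and Lgals7 overlap a gene on the other strand, so their counts are less certain.

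Of the 10380 genes with at least 200 UMIs, 1947 lay at least 0.5 log2 higher in Idoxuridine and 436 at least 0.5 log2 lower, and 5326 (51.3%) lay within 0.25 log2. The higher share of these counts, 81.7%, was 49.9% with TMM scaling (1259 higher, 1262 lower) and 68.3% with median-of-ratios scaling (1556 higher, 721 lower). TMM scaling shifted the median ratio of all genes by -0.21, from 0.09 to -0.12. Under 4 other scalings 11 of 30 list medians changed sign at least once, and for these the TMM value is given beside the main one, while among 141 named genes only Eomes did so. The ratio also ran with abundance, from a median of 0.42 in the lowest eighth of genes to -0.06 in the highest, so lists were set against random lists of similar expression.

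General pluripotency factors were lower in the Idoxuridine library. Of 14 measured members 5 lay at least 0.5 log2 lower and 2 higher, and the median log2 ratio of -0.43 was below those of all 10000 matched random lists (percentile 0). Sox2 stood at 338 CPM (333 to 344) in DMSO and 192 CPM (187 to 197) in Idoxuridine, a log2 ratio of -0.82. Dppa4 (-0.70), L1td1 (-0.67) and Tdgf1 (-0.62) were lower as well. Pou5f1, which encodes the central pluripotency factor Oct4, stood at 2072 CPM (2058 to 2086) and 1620 CPM (1606 to 1635), a log2 ratio of -0.36 that does not reach 0.5 in size. Naive pluripotency genes had a median of -0.28 (percentile 0), with 6 of 20 members at least 0.5 log2 lower and 3 higher. The members that differed most went both ways, with Tcl1 and Fgf4 (-0.86) lower and Dppa3 and Fgfbp1 (1.42) higher, while Nanog (-0.40), Esrrb (-0.42) and Klf4 (-0.20) differed by less. Per cell, the general pluripotency list summed to a median of 170 UMIs in DMSO and 128 in Idoxuridine at the fixed depth, and 10.96% of Idoxuridine cells were above the DMSO median.

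**Figure D1:**
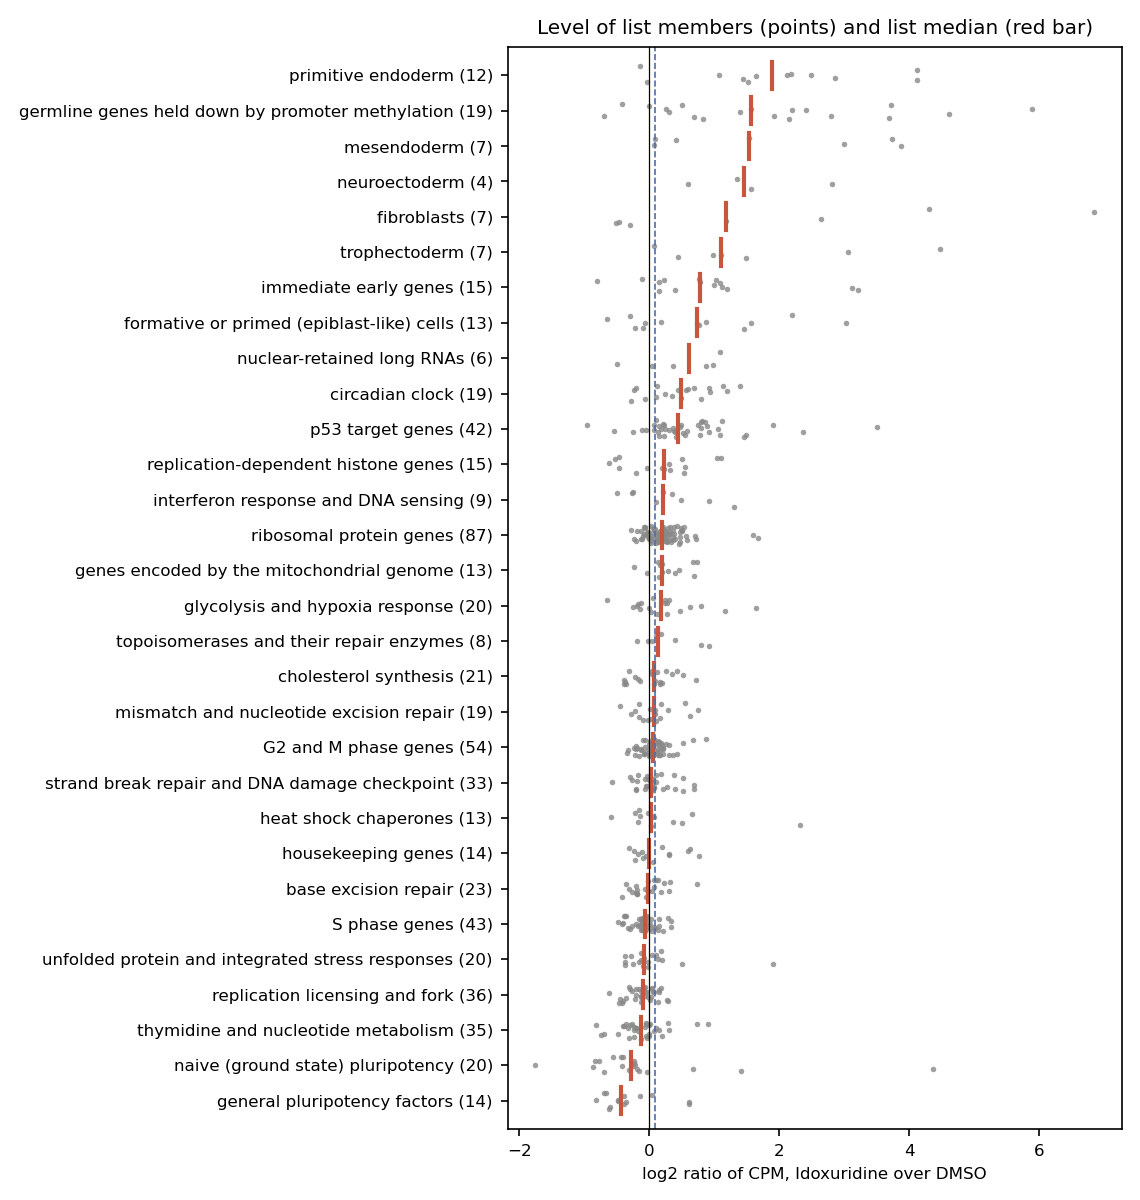
Log2 ratio of CPM, Idoxuridine over DMSO (horizontal axis), for the members of each of 30 gene lists, as grey points with random vertical offsets, with the number of measured members in parentheses, the list median as a red bar, and the median of all genes (0.09) as a dashed line. List medians run from -0.43 for general pluripotency factors to 1.88 for primitive endoderm genes.

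Markers of other cell fates were higher in the Idoxuridine library, mostly from low levels. In the primitive endoderm list 10 of 12 members lay at least 0.5 log2 higher and none lower (median 1.88, percentile 100), among them Amn (4.12), Dab2 (2.48), Srgn (2.12) and Serpinh1, a collagen chaperone gene that stood at 23.4 CPM (21.9 to 24.9) and 106 CPM (102 to 109). Formative or primed genes had a median of 0.74 (percentile 99.9, 7 of 13 higher and 1 lower), with Cldn6 (3.03), the DNA methyltransferase gene Dnmt3a (1.45), Etv4 (0.88) and Pim2 (0.77). Trophectoderm genes had a median of 1.10 (percentile 99.9, 5 of 7 higher), with Ascl2 (3.06) and the lineage regulator Cdx2 (1.49). Mesendoderm genes had a median of 1.54 (percentile 98.1, 4 of 7 higher), with the Wnt ligand gene Wnt3 (3.87) and T, which encodes Brachyury, at 1.86 CPM (1.47 to 2.33) in DMSO and 14.9 CPM (13.6 to 16.3) in Idoxuridine. Eomes in this list stood at 6.59 CPM (5.83 to 7.43) and 6.93 CPM (6.02 to 7.93), with overlapping intervals, and its ratio of 0.07 was -0.14 with TMM scaling. All 4 measured neuroectoderm genes were higher (median 1.46, percentile 96.2), among them Nes (1.56) and Tubb3 (0.59). Those measured were 12 of 18 primitive endoderm, 13 of 15 formative or primed and 7 of 11 trophectoderm genes. For mesendoderm and neuroectoderm they were 7 of 13 and 4 of 13. List totals differed by less than the medians. In DMSO and Idoxuridine they were 404 and 525 CPM for primitive endoderm and 329 and 449 CPM for formative or primed genes. Totals were 154 and 268 CPM for trophectoderm, 19.2 and 49.4 CPM for mesendoderm and 134 and 212 CPM for neuroectoderm genes.

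The fibroblast list had a median of 1.17 (percentile 97.3), with 3 of 7 measured members, out of 16 genes, higher and 1 lower. The lower one was the abundant Vim (-0.51), Timp1 stood at -0.46 and Fn1 at -0.30, and the list total was 781 CPM in DMSO and 578 CPM in Idoxuridine. In the list of 2-cell-embryo-like genes 2 genes reached 50 UMIs, so it has no median, and Gm5662 was the only 1 of these 2 past 0.5 log2 with separate intervals.

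The p53 target genes were higher in the Idoxuridine library, with 19 of 42 members at least 0.5 log2 higher and 2 lower, and a median of 0.44 above all 10000 matched lists (percentile 100). The growth arrest gene Rprm had a log2 ratio of 3.50 (3.03 to 4.01), the cell death genes Perp, Pmaip1 and Bbc3 had ratios of 1.90, 1.49 and 1.46, and Bbc3 stood at 37.4 CPM (35.6 to 39.3) and 103 CPM (99.2 to 106). Mdm2, which encodes the ubiquitin ligase of p53, stood at 92.9 CPM (90.0 to 96.0) and 169 CPM (164 to 174), a ratio of 0.86. Cdkn1a, which encodes the cell cycle inhibitor p21, differed less, at 206 CPM (202 to 211) and 240 CPM (235 to 246), a ratio of 0.22. Per cell, p53 targets summed to a median of 70 UMIs in DMSO and 90 in Idoxuridine, and 77.6% of Idoxuridine cells were above the DMSO median.

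Genes of DNA repair and synthesis differed little as groups under the main scaling. With TMM, which shifts all genes by -0.21, medians were -0.24 for base excision repair and -0.33 for nucleotide metabolism. They were -0.31 for replication and -0.28 for S phase genes. Base excision repair genes had a median of -0.03 (percentile 13.99), with 1 of 23 members, the glycosylase gene Neil3 (0.74), past 0.5 log2. Apex1, which encodes the main endonuclease of this pathway, stood at 393 CPM (387 to 399) and 344 CPM (338 to 351), a ratio of -0.19. Strand break repair and checkpoint genes had a median of 0.03 (-0.18 with TMM; percentile 25.5), with Rad51c (0.69), Rad50 (0.52) and Trp53bp1 (0.52) higher and Hus1 (-0.57) lower, and 29 of 33 in neither group. Mismatch and nucleotide excision repair genes had a median of 0.07 (-0.14 with TMM; percentile 51.5), with Ercc5 (0.74), Ercc6 (0.63) and Xpa (0.55) the 3 of 19 that were higher. Nucleotide metabolism genes had a median of -0.12 (percentile 2.69). Among them the uridine phosphorylase gene Upp1 (-0.82) and the uridine-cytidine kinase gene Uck2 (-0.74) were lower, and Impdh1 (0.90) and the deoxycytidylate deaminase gene Dctd (0.74) were higher. Tk1, which encodes the thymidine kinase that phosphorylates thymidine and its analogues, stood at 122 CPM (118 to 125) and 92.8 CPM (89.4 to 96.3), a ratio of -0.39. Replication genes had a median of -0.10 (percentile 7.16), with Gins1 (-0.62) as the only 1 of 36 past 0.5 log2, and S phase genes a median of -0.07 (percentile 12.2) with none of 43 past it. The G2/M median was 0.06 (-0.15 with TMM; percentile 98.0), with Cenpf (0.87), Fam64a (0.67) and Ckap2 (0.51) the 3 of 54 that were higher. Topoisomerase genes had a median of 0.14 (-0.07 with TMM; percentile 78.8), with Top1mt (0.91) and Top2b (0.80) higher. Replication-dependent histones had a median of 0.23 (percentile 26.3), with Hist4h4 at 1.04, and 4 of 15 members were higher.

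Germline genes that promoter methylation holds down were higher, with 11 of 19 members at least 0.5 log2 higher, 1 lower, and a median of 1.56 (percentile 100). Dazl, an RNA-binding protein gene of germ cells, stood at 6.66 CPM (5.90 to 7.50) in DMSO and 86.3 CPM (83.0 to 89.7) in Idoxuridine, and had a UMI in 12.2% and 49.9% of cells at the fixed depth. Tex101, Taf7l (3.72) and the RNA helicase gene Ddx4 (2.41) were higher as well. Immediate early genes, which also respond to cell dissociation, had a median of 0.77 (percentile 99.99), with 9 of 15 higher and 1 lower, among them Fos (3.21), Zfp36 (1.20), Egr1 (1.13) and Jund (1.09). Clock genes had a median of 0.48 (percentile 96.5), with 9 of 19 higher and none lower. Bhlhe40 (1.39), Arntl2 (1.14), Cry1 (0.94) and Nr1d2 (0.92) had the highest ratios among members with at least 200 UMIs, and Cry1, a repressor of the clock loop, stood at 28.5 CPM (26.9 to 30.2) and 54.5 CPM (51.9 to 57.2). Per2 had no UMI in DMSO and 0.394 CPM (0.204 to 0.688) in Idoxuridine. That is 5.36-fold higher against the floor of 3 counts, which is not a lower bound, as the counting interval of the log2 ratio reached down to 1.90.

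Nuclear-retained RNAs, which can be a sign of lost cytoplasm, were higher, with a median of 0.62 (percentile 100) and with 3 of 6 higher and 1 lower. Whether lost cytoplasm lies behind the rise was not tested, and the members Meg3 and Kcnq1ot1 are also imprinted genes. Malat1 stood at 2315 CPM (2300 to 2330) and 4241 CPM (4218 to 4264), with Snhg11 at 1.09, Neat1 at 0.98 and Gm26917 at -0.50. Per cell these RNAs made up a median of 0.319% of UMIs in DMSO and 0.507% in Idoxuridine. Only spread, not level, was compared in cells of a similar share. How far RNA quality enters the level differences of pluripotency, other cell fate and p53 target genes is therefore open. The mitochondrially encoded median was 0.19 (percentile 99.1) and the ribosomal protein median 0.20 (percentile 100), and both were lower with TMM scaling, at -0.02 and -0.01. Heat shock chaperones had a median of 0.02 (-0.19 with TMM; percentile 74.0), with Hspa1a at 2.32 and the abundant Hspb1 at -0.60. Genes of the unfolded protein and integrated stress responses had a median of -0.09 (percentile 7.81), with Ddit4 (1.90) and Dnajb9 (0.50) higher and 18 of 20 in neither group. Glycolysis and hypoxia genes had a median of 0.18 (-0.04 with TMM; percentile 98.5), with Egln3 at 1.64, Pgk1 at 0.63 and Pdk1 at -0.66. Cholesterol synthesis genes had a median of 0.08 (-0.13 with TMM; percentile 83.2), with Idi1 at 0.73. Interferon response genes had a median of 0.21 (-0.00385 with TMM; percentile 56.1), with the DNA sensing gene Tmem173 at 0.92 and Ddx58 at -0.50. Housekeeping genes had a median of 0.00 (-0.21 with TMM; percentile 63.5), with Actg1 at 0.76, B2m at 0.62, Actb at -0.23 and Gapdh at -0.20.

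The comparison of spread asks how much more, or less, single cells differed from each other in the Idoxuridine library. Mitochondrially encoded and ribosomal protein genes are left to the list medians, and among the other genes the largest difference at a similar level was in Sat1, which encodes the spermidine/spermine acetyltransferase that breaks down polyamines. Its mean at the fixed depth was 4.25 UMIs per DMSO cell and 5.03 per Idoxuridine cell, and its Fano factor was 1.54 and 5.46. Lgals3, a galectin gene, had means of 0.879 and 0.768 and Fano factors of 1.32 and 3.97. Nr0b1, which encodes the pluripotency regulator Dax1, had Fano factors of 1.84 and 4.89, and Zfp42, the stem cell marker gene for Rex1, had 2.18 and 4.74. The abundant apolipoprotein gene Apoe had means of 53.6 and 47.8 UMIs and Fano factors of 6.34 and 16.0.

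The others with the largest log2 Fano ratios at a similar level were the imprinted gene Mest (1.38), Ptms (1.30), the creatine kinase gene Ckb (1.28, but -0.0899 with raw UMIs), the glutamine synthetase gene Glul (1.24) and the imprinted RNA gene Meg3 (1.13). Among genes within 0.5 log2 in level, outside the mitochondrially encoded and ribosomal protein genes, the lowest ratios were smaller in size, at -0.43 for Sgce and Wwc1, -0.42 for Spint2, -0.40 for Rec8, -0.39 for Dcxr, -0.35 for Emp1, -0.33 for Dhx16, -0.29 for Slc25a4 and -0.26 for Cdyl2 and Psrc1.

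Over 7316 genes the median log2 Fano ratio was 0.08, and the Fano factor was higher in Idoxuridine for 5797 of them (79.2%, binomial interval 78.3% to 80.2%). The median Fano factor was 1.08 in DMSO and 1.14 in Idoxuridine, both close to the value of 1 that counting alone gives. With the counting part taken off, the median CV² was 0.0585 in DMSO and 0.103 in Idoxuridine, and the median log2 ratio over 6580 genes was 0.67, or 1.59-fold. The median log2 CV² ratio was between 0.60 and 0.72 in each level class below a mean of 20 UMIs per cell, and 0.28 in the 161 genes above it. Genes are not replicates, and the binomial interval treats them as independent. Without thinning, raw UMIs gave a median log2 Fano ratio of -0.00011 and a log2 CV² ratio of 0.23, and in the simulation unchanged genes had a median Fano ratio of -0.13 without thinning, since the DMSO library was deeper.

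**Figure D2:**
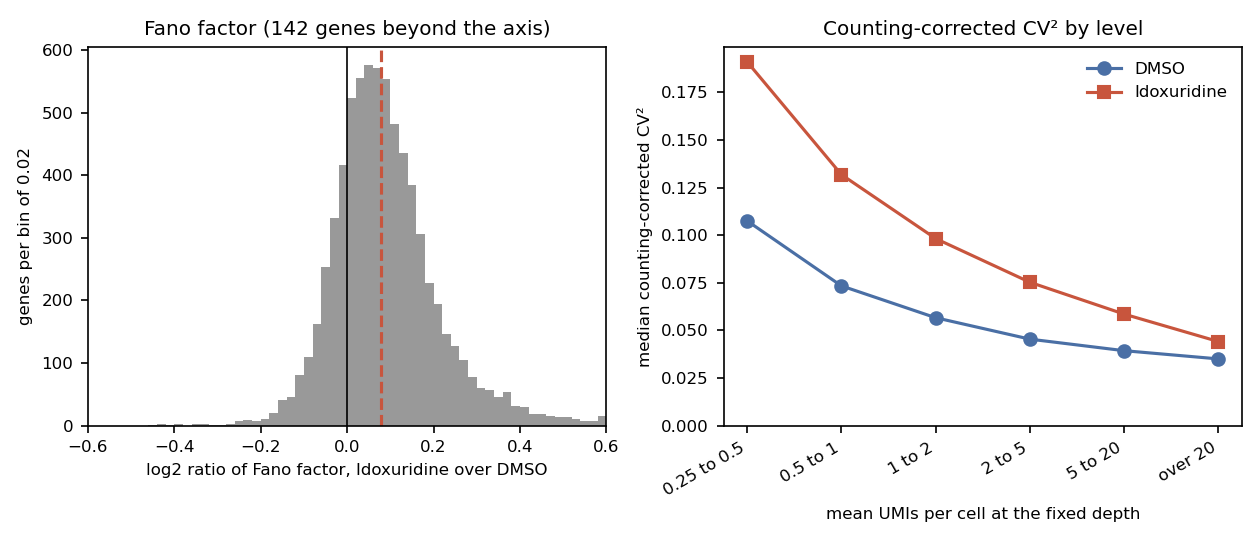
Left, number of genes per bin of 0.02 in the log2 ratio of the Fano factor, Idoxuridine over DMSO, for 7316 genes, with the median of 0.08 as a dashed line. Right, median counting-corrected CV² in each library by class of mean UMIs per cell at the fixed depth, with DMSO as circles and Idoxuridine as squares, where the Idoxuridine value is the higher one in all 6 classes.

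Pluripotency genes had among the largest differences in spread. All 14 general pluripotency factors had a higher Fano factor in Idoxuridine (median log2 ratio 0.38, percentile 100), with Zfp42 (1.12), Pou5f1 (0.74), Tdgf1 (0.70), Rif1 (0.49) and Sox2 (0.38). The counting-corrected CV² of Pou5f1 was 0.0230 in DMSO and 0.0667 in Idoxuridine. All 16 naive pluripotency genes past the mean filter were also higher (median 0.57, percentile 100), with Nr0b1 (1.41), Fgfbp1 (1.35), Nanog (0.81), the threonine dehydrogenase gene Tdh (0.81), Klf4 (0.62) and Esrrb (0.08). The mean of Fgfbp1 was also higher, at 1.92 UMIs per DMSO cell and 5.21 per Idoxuridine cell, and its log2 CV² ratio was only 0.22. The median log2 CV² ratio was 1.31 for the general and 1.83 for the naive list. Nanog had a CV² of 0.110 and 0.402. These directions depend on thinning for some genes, since with raw UMIs Pou5f1 stood at -0.50, Tdh at -0.29, Zfp42 at -0.01 and the general list median at -0.06.

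Other lists with high Fano medians were the nuclear-retained RNAs (0.64, percentile 100), with Neat1 (1.13) and Malat1 (0.93, but a log2 CV² ratio of 0.11 with a higher mean), and trophectoderm (0.59 over 3 genes, percentile 99.97), in which Tfap2c (0.61) and Krt8 (0.59) were higher and Cdx2 (-0.62) was lower. The median was 0.40 for 3 fibroblast genes (percentile 98.9; Timp1, 0.45), 0.29 for immediate early genes (percentile 99.96; Klf6, 0.76), 0.28 for formative or primed genes (percentile 99.9; Fst, 0.57), 0.27 for germline genes (percentile 99.3; Tex19.1, 0.65), 0.24 for clock genes (percentile 99.9; Csnk1e, 0.56, and Cry1, 0.29), 0.23 for glycolysis and hypoxia (percentile 98.7; the glucose transporter gene Slc2a3, 0.67), 0.20 for cholesterol synthesis (percentile 99.95; Hmgcs1, 0.80, and Nsdhl, 0.72) and 0.21 for interferon response (percentile 97.7; Oas1a, 0.43). With no thinning, raw UMIs gave negative medians for the fibroblast and the glycolysis and hypoxia lists. The median log2 CV² ratio of all genes was 0.67. It was lower for nuclear-retained RNAs (0.55), immediate early (0.52), glycolysis and hypoxia (0.51), trophectoderm (0.38) and germline genes (-0.31). It was higher for fibroblast (1.51), interferon response (0.96), cholesterol synthesis (0.83), clock (0.81) and formative or primed genes (0.81). Primitive endoderm, mesendoderm, neuroectoderm and 2-cell-embryo-like lists had under 3 genes past the mean filter, with Tubb3 at 1.37 and the matrix gene Sparc at 0.58, but -0.14 with raw UMIs.

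In Fano factor, stress, repair and cycle lists lay nearer to the median of all genes. It was 0.20 for heat shock (percentile 87.2; Hsp90aa1, 0.93, but -0.35 with raw UMIs), 0.18 for housekeeping (percentile 92.1; Actb, 0.08, and Gapdh, 0.26), 0.14 for S phase (percentile 95.9; Rrm2, 0.42), 0.12 for nucleotide metabolism (percentile 77.2; Upp1, 0.87, and Tk1, -0.12), 0.12 for the stress responses (percentile 71.3; Ddit4, 0.83), 0.11 for replication (percentile 71.4; Rpa2, 0.27) and 0.08 for base excision repair (percentile 47.8; Hmgb1, 0.41, and Apex1, 0.17). The p53 targets had a median of 0.09 (percentile 51.5), with Sfn (0.72) higher, Perp (-0.44) and Dcxr (-0.39) lower, Cdkn1a at 0.20 and Mdm2 at -0.09. Medians were 0.05 for strand break repair (percentile 12.9; Brca2, 0.44), 0.05 for G2/M (percentile 0.18, and -0.0388 with raw UMIs; Cenpf, 0.51), 0.04 for mismatch and nucleotide excision repair (percentile 8.01), 0.03 for histones (percentile 22.9; Hist1h1a, -0.13) and 0.02 for topoisomerases (percentile 6.79; Top2b, 0.24). Ribosomal protein genes had a median of 0.06 (percentile 0), but -0.21 with raw UMIs. The median log2 CV² ratio was of the other sign for germline genes (-0.31), p53 targets (-0.13), histones (-0.14) and ribosomal protein genes (-0.0626), and so was that of Tex19.1 (-1.23), Ddit4 (-0.57) and Cenpf (-0.21). For base excision repair (0.91) and strand break repair (0.70) the list median was above the 0.67 of all genes. In the other lists named here it was at most 0.65. The mitochondrially encoded median was -1.57 (percentile 0), but -0.02 without the 3 cells above a mitochondrial share of 10%.

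**Figure D3:**
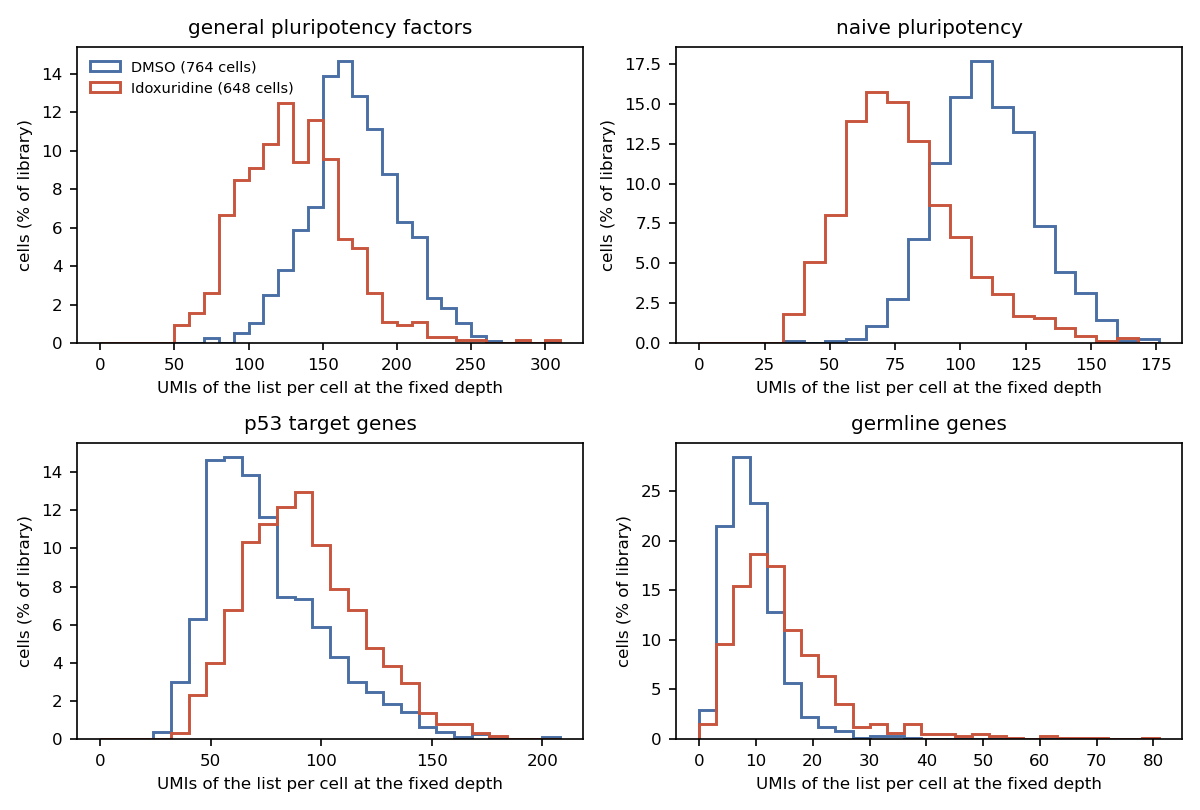
Share of cells (vertical axis, percent of the library) by the UMIs of a gene list per cell at the fixed depth (horizontal axis), for 764 DMSO cells and 648 Idoxuridine cells. The medians were 170 and 128 UMIs for general pluripotency factors, 109 and 74 for naive pluripotency, 70 and 90 for p53 targets and 8 and 12 for germline genes.

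The comparison of cells asks how the libraries differed in cell cycle calls, similarity and marker-positive cells. At the fixed depth 50.8% of DMSO cells (47.2% to 54.4%) and 43.8% of Idoxuridine cells (40.0% to 47.7%) were called S phase, and 47.9% (44.3% to 51.5%) and 54.0% (50.1% to 57.9%) G2/M, with 10 and 14 cells called G1. Without thinning the S shares were 52.3% and 44.7% and the G2/M shares 44.5% and 48.7%. A phase call is a range of a score, and 79 of 764 DMSO cells and 72 of 648 Idoxuridine cells lay within 0.05 of a boundary. The median correlation between cells of a library was 0.720 in DMSO and 0.692 in Idoxuridine.

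Mesendoderm genes reached at least 3 UMIs in 1.83% of DMSO cells (1.01% to 3.06%) and 15.0% of Idoxuridine cells (12.3% to 18.0%), and without thinning in 10.5% and 29.8%. The shares were 56.8% (53.2% to 60.4%) and 83.6% (80.6% to 86.4%) for trophectoderm genes and 51.4% (47.8% to 55.0%) and 63.7% (59.9% to 67.4%) for neuroectoderm genes, and without thinning 80.9% and 91.1%, and 74.4% and 78.4%. Krt8 held 3816 of the 6277 trophectoderm UMIs in DMSO and 3864 of 8166 in Idoxuridine. The trophectoderm share thus leans on this keratin gene and is not a share of trophectoderm cells. The neuroectoderm share rests on Tubb3, since without this gene, a check chosen after the values were seen, it was 0.524% (0.143% to 1.34%) and 2.78% (1.65% to 4.35%), and 50% of Idoxuridine cells were above the DMSO median of the whole list. The 2-cell-embryo-like genes reached 3 UMIs in 0 of 764 DMSO cells (exact binomial upper limit 0.482%, and 0.393% at a floor of 3 cells). They did so in 18 of 648 Idoxuridine cells (2.78%, 1.65% to 4.35%), and without thinning in 0.123% and 4.04%. Of these 18 cells 16 had at least 3 UMIs of Gm5662 alone, and no cell reached 3 UMIs without that gene, a check chosen after the values were seen, so the cells are not named as a type. Naive, formative or primed, primitive endoderm and fibroblast lists reached 3 UMIs in over 95% of the cells of both libraries and do not separate them. Free RNA was not measured, since neither library held a cell type that should lack these genes, and its part in these shares is open.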

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

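The alternatives were fixed before the data were examined, except for 7 that were chosen after the values were seen: genes matched on level, cells without the least typical 5%, cells of 30000 to 50000 UMIs, cells of a similar nuclear-retained share, the weakly expressed genes per cell under TMM, neuroectoderm without Tubb3, and 2-cell-embryo-like genes without Gm5662. No paired analysis was possible because each treatment had 1 library and no result came from a test. A turn of direction was counted only for single-gene levels past the size limit and for single-gene Fano ratios of at least 0.5 log2 in size. For list medians it was counted only where the list lay outside the central 95% of its random lists. By this count all 987 alternative values of single-gene levels kept their direction. So did 204 of 210 list level medians, 398 of 408 list Fano medians and 1790 of 1801 single-gene Fano ratios. Sign changes of smaller values count as kept here, including some of the 11 of 30 list medians that changed sign under other scalings. For single-gene levels, a scaling that shifts all genes alike could not turn a value past the limit. The largest such shift, -0.21 with TMM, is under 0.5 in size. Genes short of the limit are among the 987 and could not count as turned. That count therefore says little on robustness. Without thinning the order of the libraries turned for 2 marker shares, formative or primed (99.3% in DMSO and 98.4% in Idoxuridine) and primitive endoderm (99.6% and 99.3%). TMM scaling gave 1259 genes higher and 1262 lower, and turned the level medians of G2/M (-0.15), glycolysis and hypoxia (-0.0352), mitochondrially encoded (-0.0189) and ribosomal protein genes (-0.00822), by its shift of -0.21. Median-of-ratios scaling gave 721 genes lower and a G2/M median of -0.0367, and the mean of per-cell CPM a G2/M median of -0.00160. A minimum of 50 UMIs gave 3099 genes higher, and one of 1000 UMIs gave 678 higher and 287 lower, since other numbers of genes were counted. With raw UMIs and no thinning the median Fano ratio was -0.00011, the share of genes higher 49.9% and the CV² ratio 0.23. The same setting turned the Fano medians of general pluripotency (-0.0553), fibroblast (-0.0345), G2/M (-0.0388), glycolysis and hypoxia (-0.0369) and ribosomal protein genes (-0.21), and the ratios of Zfp42 (-0.00914), Tdh (-0.29), Sparc (-0.14), Hsp90aa1 (-0.35), Ckb (-0.0899) and Pou5f1 (-0.50). Unchanged genes of the simulation had a ratio of -0.13 without thinning, so the deeper DMSO library alone pulls raw values down. With UMIs scaled to a common total the Fano ratio was 0.37 and the share 97.8%. Thinning to the 25th percentile depth gave 0.0848 and 76.5%, a thinned mean of at least 1 gave 0.10 and 83.9%, and one of at least 0.05 gave 0.0676, 76.0% and a CV² ratio of 0.62. Fano ratio, share and CV² ratio were 0.23, 61.6% and 0.52 in the few G1 cells, 0.10, 77.2% and 0.83 in S cells, and 0.0539, 68.8% and 0.48 in G2/M cells. They were 0.0664, 78.2% and 0.60 in genes matched on level, 0.10, 75.3% and 0.70 in cells of 30000 to 50000 UMIs, and 0.0623, 71.3% and 0.55 in cells of a similar nuclear-retained share. That setting also turned the Fano medians of G2/M (-0.000266) and nuclear-retained RNAs (-0.0183) and the ratios of Malat1 (-0.105) and Neat1 (-0.0335), the last 3 being part of the share it holds similar. The CV² ratio was 0.70 without the least typical cells, and without cells far from the median UMIs it was 0.70 with a Fano ratio of 0.0824. The mitochondrially encoded Fano median was 0.34 in S cells and 0.33 in cells of 30000 to 50000 UMIs. In G2/M cells the ribosomal protein median was -0.0656 and the ratio of Ddit4 -0.0509, and in G1 cells the ratios of Klf4 and Tuba1a were -0.0215 and -1.268. Without thinning the G2/M share of Idoxuridine cells was 48.7%. Apart from scaling, gene numbers and raw depth, the cause was not tested.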

Other observations

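The gene groups of these first 2 paragraphs, and the tests by depth, by atypical cells, by nuclear-retained share and by a subset of cells further on, were chosen only after the values were seen. Imprinted genes were higher in the Idoxuridine library, with 10 of 20 members at least 0.5 log2 higher, none lower, and a median of 0.75 (percentile 100). Beside Phlda2 and Ascl2, the amino acid transporter gene Slc38a4 (1.96 CPM, 1.55 to 2.44, and 13.4 CPM, 12.1 to 14.8) and the growth inhibitor gene Cdkn1c (3.06 CPM, 2.55 to 3.65, and 20.3 CPM, 18.7 to 22.0) had the highest ratios among members with at least 50 UMIs. Nnat (1.56), Peg10 (1.23) and Peg3 (1.03) were higher as well, and Snrpn stood at -0.47, short of 0.5 in size. Their Fano median was 0.32 (percentile 100), and the Fano factor of Peg3 was 1.51 in DMSO and 5.01 in Idoxuridine. Genes of simple epithelia had a median level ratio of 1.32 (percentile 100) and a Fano median of 0.41 (percentile 99.99). Their median log2 CV² ratio was 0.28, below the 0.67 of all genes, so with counting taken off they did not stand out in spread. Krt19, a keratin gene, stood at 1.86 CPM (1.47 to 2.33) and 31.9 CPM (29.97 to 34.02), and the adhesion gene Epcam at 81.1 CPM (78.4 to 84.0) and 265 CPM (259 to 271), while Cdh1, which encodes E-cadherin, differed by 0.04.

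Genes of the Nodal and Lefty pathway went both ways, with 5 of 11 members lower, 2 higher, 4 in neither group, a median of -0.30 (percentile 0.065) and a Fano median of 0.19 (percentile 95.4). Lefty1 (-1.24) and Gdf3 (-0.98) were lower like Lefty2, Nodal itself differed by 0.14, and Skil was higher (1.37). Lysosomal genes had a level median of 0.02 (percentile 67.6) and a Fano median of 0.25 (percentile 99.94). The protease gene Ctsc had a Fano factor of 1.73 in DMSO and 3.62 in Idoxuridine.

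The higher spread between cells was weighed against 5 technical or compositional explanations. In cells of 30000 to 50000 UMIs the median log2 CV² ratio was 0.70, and without the least typical 5% of cells it was 0.70, which depth or a few atypical cells as the whole cause would have brought below 0.1. The lowest ratio within a called phase was 0.48, in G2/M cells, against 0.67 in all cells. A different mix of phases is thus not the whole cause, but a part is open. Nuclear-retained RNAs were also higher in level and spread, and in cells of a similar share of them (medians 0.373% and 0.419%) the ratio was 0.55, so this possible sign of RNA quality is not the whole cause but a part is open. With 10 principal components removed from each library the ratio was 0.81 over 5060 genes, against 0.59 over 5921 genes with none removed. The share of genes above counting fell from 85.9% to 76.7% in DMSO and from 92.6% to 87.8% in Idoxuridine. The median log2 Fano ratio was 0.0842 with 10 removed and 0.0830 with none. Since the gene set changed, and more so through DMSO, this check cannot decide on a few shared axes. Idoxuridine and any other difference in culture, loading or preparation between these single libraries cannot be told apart.

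The higher level of weakly expressed genes, with a median log2 ratio of 0.42 in the lowest eighth (0.21 with TMM), was weighed next. If background added to every gene had been the only difference, under 2% of these genes would lie below the median of the most abundant eighth with their whole counting interval, and 7.63% did. Since 567 of these genes lay at least 0.5 log2 higher and 67 lower, background as a part of the rise stays open. A subset of strongly altered cells would leave under 75% of Idoxuridine cells above the DMSO median cell in the UMIs of these genes, and the share was 98.1%, but 88.7% with TMM against a bound of 90%, so a subset stays open. Priming inside long genes or genomic DNA would tie the ratio to gene span, and the Spearman correlation was 0.0615. The treatment and other differences between the libraries stay open as well.

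Ribosomal protein genes, with a median ratio of 0.20, are short, so a length bias between the libraries was tested on other short genes. The 440 other protein-coding genes no longer than the median ribosomal protein gene (1059 bases) had a median of -0.0200 (percentile 0), where a length bias as the whole cause would have given at least 0.15. Against random lists these short genes thus lay low, where ribosomal protein genes lay high (percentile 100). Among the 87 ribosomal protein genes the shorter ones had the higher ratios (Spearman correlation with length -0.249), against 0.149 over all genes with at least 200 UMIs, so a part played by length within this group is open. The direction itself rests on scaling, with a median of -0.01 under TMM.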
